A study of Homo sapiens with 2 samples.

How the data were processed

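CUT&RUN was performed on cytotrophoblasts selected from human placental villous tissue with an antibody against ITGA6, with 1 library for an anti-PRMT1 antibody and 1 for a control IgG. Per the labels' protocols, libraries were sequenced as paired 101 bp reads. The labels name both a ChIP and an RNA library kit, and which of them was used is not given in the sources used here.

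The file analysed is a list of intervals of the PRMT1 library with position, name, score and strand columns and no header, deposited by the authors. The score of each interval is the authors' own value. What it measures is not given in the sources used here, and it was used only to describe, rank and filter intervals within this list. Scores are bounded at 1000, so 34.3% of intervals are tied at the ceiling and cannot be ranked by score. Coordinates are on hg38, per the submitters' processing notes. The aligner, the caller of the intervals, its threshold, the treatment of duplicate reads and any use of the IgG library as background are not given in the sources used here. A looser threshold or a caller that joins neighbouring summits would give more or wider intervals, so the number of intervals and their widths are properties of that processing as well as of the cells. The IgG library was not analysed here, and no background measured in the same way stands beside the values. The list gives no read counts, so the depth is unknown. Wilson 95% intervals of shares cover counting error only, since intervals and genes are not replicates.

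Start positions were converted from 0-based to 1-based. Intervals and genes on the Y chromosome and the gene XIST were left out. Genes were taken from a RefSeq gene table of GRCh38, the same build, with 59093 genes used. It gives the start and end of each gene but neither strand nor transcripts, and no genome sequence was used here. A gene's promoter was therefore replaced by its boundaries, and exon, intron and UTR annotations, start sites of single transcripts, base composition and motif content were not analysed here. A start site inside a gene is missed by this definition, and an interval at a 3′ end counts. An interval was placed by its centre within 1 kb of a boundary of a protein-coding or lncRNA gene, otherwise inside a gene, otherwise intergenic. A gene counted as having an interval when any interval overlapped the 1 kb on either side of either boundary by at least 1 bp, and its width was that of the widest such interval. Overlapping, antisense and closely spaced genes can share an interval, and genes with near-identical copies (CGB, CSH, PSG, histone and globin genes, FCGR3A) are uncertain because reads may not map uniquely.

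Random placement kept each interval's width and chromosome and was drawn 1000 times (200 for alternatives, 100 for gene classes and distances) between the first and last gene of a chromosome, outside stretches of at least 1 Mb without genes or intervals. The 27 gene lists, their members and the alternatives were written before the data were examined. Of 753 list entries, 751 were found as protein-coding genes, 3 list or added-list symbols through an older name. The count of members with an interval and the median width, with 0 for none, were set against 10000 random lists with the same number of protein-coding genes in each of 10 classes of gene length. Matching on promoter CpG content had been intended, and gene length, listed beforehand as another choice, took its place. Promoters rich in CpG, frequent among housekeeping genes, are therefore not balanced in these comparisons. With 1 library, percentiles describe this library and no p-values were computed.

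The named genes are the 25 protein-coding genes with the highest-scoring boundary interval, 1 gene per interval, the PRMT1 gene, and in each list up to 4 members with the highest score and the first 2 listed members without an interval. Ordering ties at the score ceiling by width was chosen after seeing the data, as were 6 further lists used in the closing section and the gene families described there. Interval positions at named genes are those of the deposited list, in hg38.

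Alternatives were the 15251 highest-scoring intervals, the 7625 widest of the 10463 tied at the score ceiling (the highest-scoring 25% had been intended, and ties were ordered by width), autosomes only, windows of 500 bp and 5 kb, other overlap rules, joining intervals closer than 1 kb and unmatched random lists. Added after seeing the data were all intervals at the score ceiling, placement over whole chromosome spans, credit to the nearest gene only, any interval inside the gene, matching on neighbouring boundaries within 10 kb, and the syncytiotrophoblast list without its near-identical families. Under nearest-gene credit both protein-coding and lncRNA genes compete, so the neighbouring gene that receives an interval can be a lncRNA gene. The procedures were tested on simulated data. Randomly placed intervals gave folds of 0.973 to 1.03 over random placement in 20 runs. With intervals seeded at 200 genes, 100% were recovered and 8.94% of other genes were touched by background. A list of 25 genes with 15 seeded reached the 100th percentile, and 100 unseeded lists had a mean percentile of 46.4. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.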

Results

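The data describe where an antibody against the arginine methyltransferase PRMT1 gave signal on chromatin of human primary cytotrophoblasts. These are the progenitor trophoblasts of the placental villus, here isolated from dissected villous tissue by magnetic selection for the surface integrin ITGA6. CUT&RUN was used, in which an antibody bound to a chromatin protein directs a nuclease to cleave the DNA beside it, and the released fragments are sequenced. The series holds 1 library made with an antibody against PRMT1 and 1 made with a control IgG, both from untreated cells. The intervals of signal listed for the PRMT1 library are described here, and the IgG library was not analysed here. The purpose given by the series title is to find the target genes of PRMT1 in these cells. With 1 library there is no replicate error and no p-value. Comparisons with randomly placed intervals or randomly drawn genes describe this library alone.

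The PRMT1 library had 30503 intervals that covered 58.2 Mb, 2.04% of the part of the genome open to random placement. Interval width had a median of 1376 bp with quartiles of 585 and 2739 bp, and ranged from 238 to 19654 bp. The authors' score of an interval ran from 30 to a ceiling of 1000, with a median of 275, and 10463 intervals (34.3%) stood at the ceiling. Wider intervals had higher scores, with a Spearman correlation of 0.872 across intervals, which are not independent replicates. The number of reads behind an interval is unknown, since the list carries no read counts.

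PRMT1 intervals gathered at the ends of genes. The centres of 12590 intervals, 41.3% (Wilson 95% interval 40.7 to 41.8), lay within 1 kb of a boundary of a protein-coding or lncRNA gene, against a mean of 5.36% (range 4.99 to 5.77) in 1000 random placements, a 7.69-fold excess. A boundary is either end of the annotated gene, because the gene table used here carries no strand. Gene interiors held 13193 intervals, 43.3% (42.7 to 43.8) against 54.8% at random, a ratio of 0.790. Intergenic sequence held 4720, 15.5% (15.1 to 15.9) against 39.9%, a ratio of 0.388. Measured to protein-coding genes alone, 22.9% of centres lay within 0.5 kb of a boundary (random 1.58%), and 5.66% lay over 100 kb away (random 34.3%). The excess over random was 12.7-fold in the 10463 intervals at the score ceiling and 3.14-fold with a window of 5 kb.

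**Figure D1:**
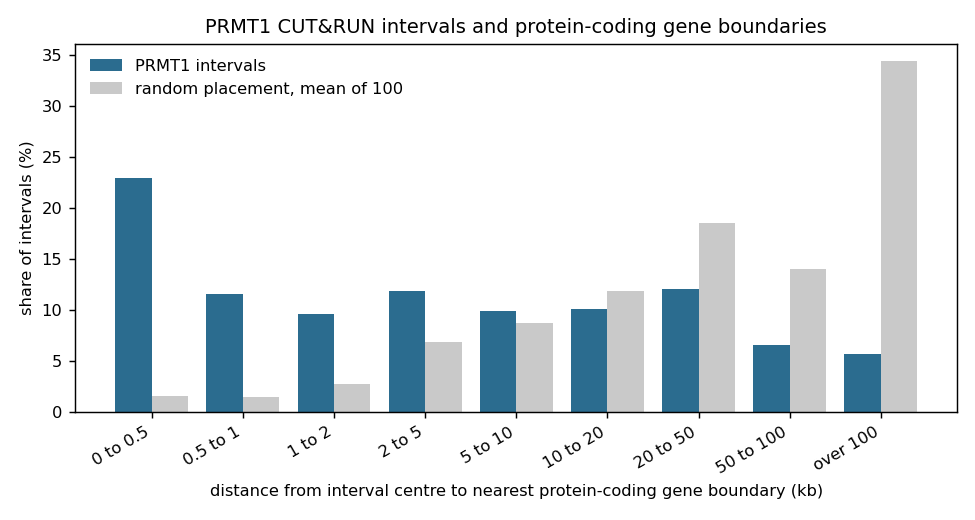
Share of the 30503 PRMT1 intervals (y axis, percent) by the distance from the interval centre to the nearest protein-coding gene boundary (x axis, kb), beside the mean of 100 random placements. The bin nearest to the boundary holds 22.9% of intervals against 1.58% at random, and the bin beyond 100 kb holds 5.66% against 34.3%.

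Intervals centred at gene boundaries had higher median scores and widths than those elsewhere. Their median score was 1000 (quartiles 300 and 1000), and 57.7% stood at the ceiling. Inside genes the median score was 115 (59 to 638), with 21.0% at the ceiling, and in intergenic sequence it was 105 (58 to 298), with 8.92% at the ceiling. Median widths were 2313 bp at boundaries, 898 bp inside genes and 722 bp in intergenic sequence. In the higher-scoring part of the list the median score no longer separated boundary intervals from the rest, since both medians reached the ceiling.

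Most protein-coding genes had an interval of the PRMT1 library at an end, with no IgG background set against it. Of 19970 protein-coding genes, 14066 had an interval overlapping the 1 kb on either side of a boundary, 70.4% (Wilson 95% interval 69.8 to 71.1), against 9.16% (8.60 to 9.87) in random placements. The widest such interval per gene had a median width of 2891 bp (quartiles 2067 and 3969). At isolated genes the signal lay mostly at a single end. Among 1620 genes of at least 10 kb with no boundary of another gene within 20 kb, 992 (61.2%) had an interval at 1 end and 11 (0.679%) at both, where independent ends would give 9.79%. Of the intervals at the score ceiling alone, 10296 genes had one at a boundary, and of the 7625 widest of these, a choice by width, 8022 genes did.

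Genes transcribed by other polymerases and non-coding genes differed widely. An interval lay at a boundary of 240 of 443 tRNA genes, 54.2% (49.5 to 58.8) against 5.04% at random. lncRNA genes had one at 4925 of 18176 (27.1%, random 7.81%), miRNA genes at 353 of 1911 (18.5%, random 4.89%) and snoRNA genes at 174 of 1196 (14.5%, random 4.60%). Transcribed pseudogenes had one at 418 of 1246 (33.5%). Other pseudogenes, at 640 of 15212 (4.21%), and immunoglobulin and T cell receptor V segments, at 5 of 248 (2.02%), lay below their random means of 5.30% and 5.0%. snRNA genes had an interval at 50 of 154 (32.5%, random 6.47%).

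Genes that mark trophoblasts did not carry PRMT1 intervals more often than other genes of their length, while markers of Hofbauer cells, the macrophages of the villus, carried them more often. Of 28 regulators and markers of trophoblast progenitors, 19 (67.9%) had a boundary interval, where random lists matched on gene length had 16 to 25 (the range without the lowest and highest 2.5% of lists). Of 30 syncytiotrophoblast genes, those of the hormone-making fused layer, 12 (40%) had one, below the random range of 14 to 24, but without 8 members of near-identical families the count of 12 of 22 lay within its range of 10 to 19. Of 20 Hofbauer cell and macrophage markers, 19 (95%) had one, above the random range of 9 to 17. Hofbauer markers exceeded trophoblast progenitor genes by 27.1 percentage points, but fell below them, at -21.4 points, when the interval's centre had to lie inside the window. By construction that rule leaves out wide intervals whose centre lies over 1 kb from a boundary. The Hofbauer intervals were wide, as described below, so the reversal cannot be told apart from their width.

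Among trophoblast progenitor genes the intervals with the highest scores were at GATA2 (8075 bp wide), a trophoblast transcription factor, and at ITGA6 (5400 bp), the integrin used for the selection, followed by SPINT1 (4679 bp) and ARID3A (4119 bp). The ITGA6 interval spanned positions 172426986 to 172432385 of chromosome 2 (hg38), over the lower end of the gene. Lower scores were listed at the boundary intervals of TEAD4 (123), GATA3 (55) and CDH1 (82), which the naming rule does not pick. GATA3 also had an interval of 4641 bp inside the gene. No boundary interval was listed at TFAP2A or ELF5, although TFAP2A had an interval of 4084 bp inside the gene and ELF5 had none. Further genes without one, named after their values were seen, included TP63 and KRT7, which had none inside the gene either. WWTR1 also lacked one at its boundaries but had one of 5455 bp inside the gene. Among syncytiotrophoblast genes ENDOU (4001 bp), SDC1 (2702 bp), TBX3 (2307 bp) and INHA (1778 bp) had the highest-scoring intervals, and CGA and CGB3, which encode the subunits of chorionic gonadotropin, had none. The 8 listed members of the CGB, CSH and PSG families, whose near-identical copies can lose reads in mapping, had no interval, and the other 22 had one at 12 (54.5%), at percentile 10.9 of random lists. Of 26 extravillous trophoblast genes, 18 (69.2%) had an interval (random 14 to 23), led by ITGA5 (8818 bp), PLAC8 (7163 bp), TCF7L2 (6915 bp) and the chemokine receptor CCR1 (5657 bp), with none at HLA-G or MMP12. With credit only to the protein-coding or lncRNA gene with the nearest boundary, the intervals at GATA2, SPINT1, INHA and TCF7L2 went to neighbouring genes. ENDOU kept one of 260 bp. The centre rule removed the intervals at GATA2, ITGA6, SPINT1, INHA, PLAC8, TCF7L2 and CCR1 and kept those of ARID3A, SDC1 and TBX3. Among intervals at the score ceiling the counts were 4 for progenitor, 2 for syncytiotrophoblast and 10 for extravillous genes, and with the centre rule 6 for syncytiotrophoblast and 10 for extravillous genes.

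The Hofbauer markers carried broad intervals. Their median width was 7131 bp, genes without one counted as 0, above all 10000 random lists, whose highest 2.5% began at 3007.5 bp. The corresponding medians were 1726.5 bp for trophoblast progenitor genes and 2199 bp for extravillous genes, both within their random ranges. The interval at CD163, the haemoglobin scavenger receptor of macrophages, was 13484 bp wide and spanned 7490803 to 7504286 of chromosome 12, across the upper boundary of the gene (7470811 to 7503777). At TYROBP, an adaptor of myeloid receptors, the interval was 12268 bp wide (chromosome 19, 35897775 to 35910042). It also covered HCST and the upper end of NFKBID. CD68 lay in an interval of 13569 bp shared with EIF4A1, SENP3 and MPDU1. PTPRC, the leukocyte antigen CD45, had an interval of 9032 bp. With credit only to the protein-coding or lncRNA gene with the nearest boundary, the intervals at CD163, TYROBP and CD68 went to neighbouring genes. The interval at PTPRC stayed, and that at CD163 touched the window of no other protein-coding gene. With the interval's centre required inside the window, PTPRC, CD163 and CD68 had none and TYROBP kept its interval. CSF1R had none at its boundaries and one of 8167 bp inside the gene. Among members with an interval, the median width at Hofbauer markers was 2.96 times that at trophoblast progenitor genes, a ratio that cannot be compared with one from the highest-scoring intervals alone, since these are wider.

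**Figure D2:**
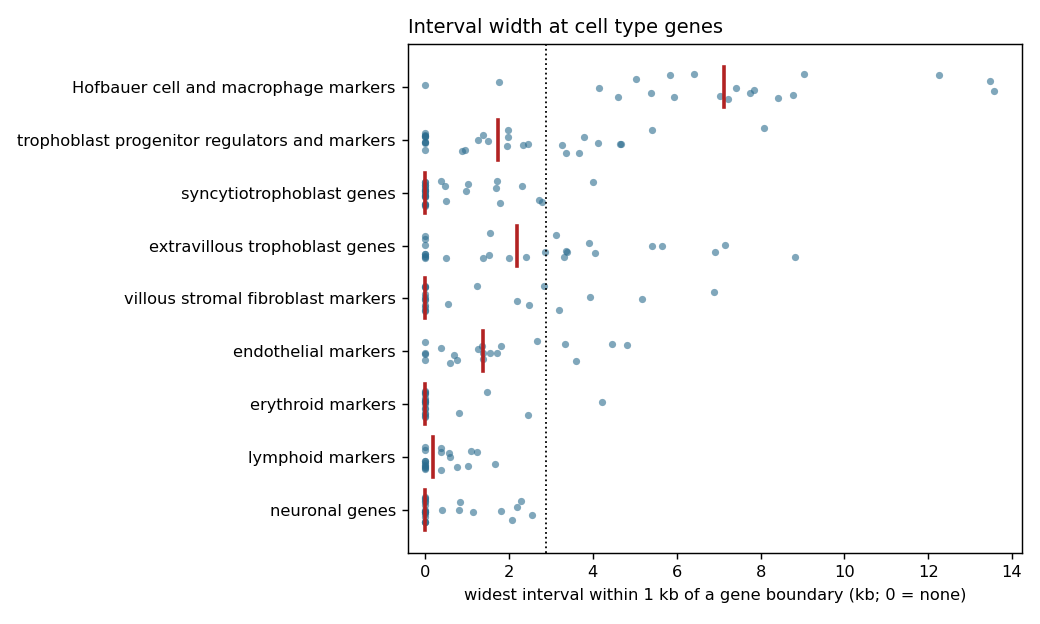
Width of the widest interval within 1 kb of a gene boundary (x axis, kb, 0 for none) for each member of the 9 cell type lists, with the median of each list as a bar and the median of all protein-coding genes with an interval, 2891 bp, as a dotted line. The Hofbauer median of 7131 bp lies to the right of the dotted line, and the medians of the syncytiotrophoblast, stromal, erythroid and neuronal lists are 0.

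**Figure D3:**
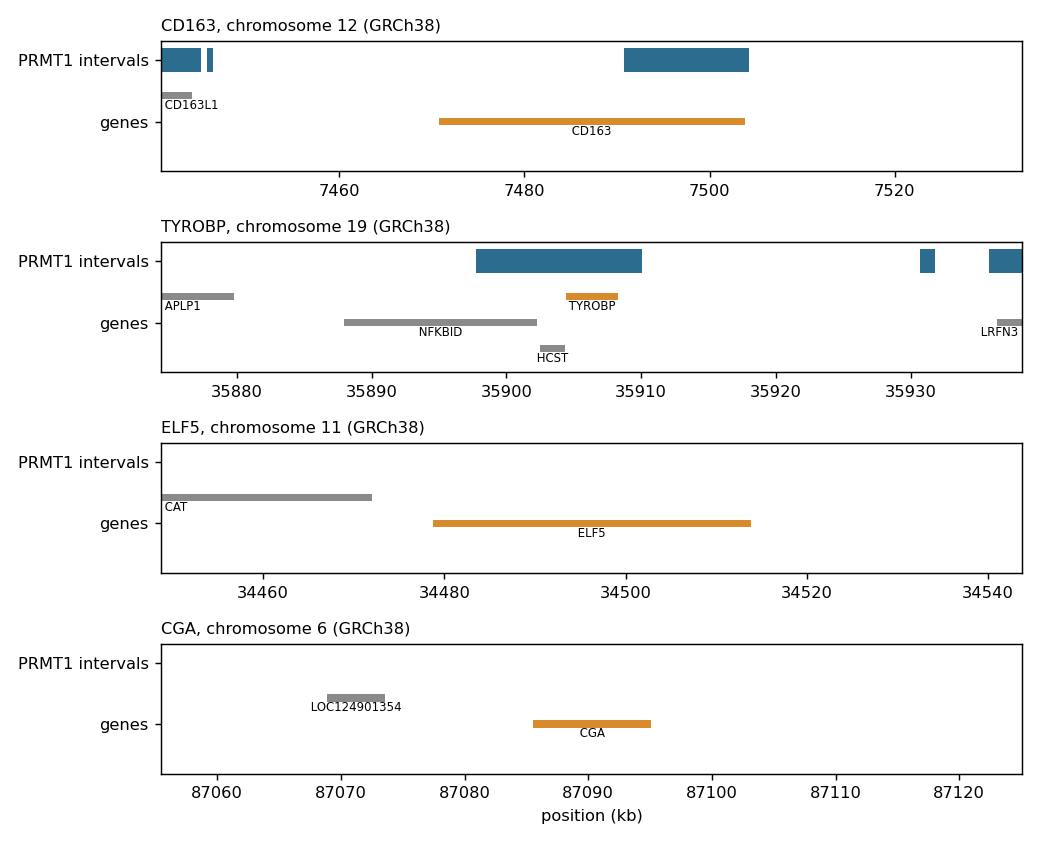
Maps of CD163, TYROBP, ELF5 and CGA with their surroundings (x axis, position in kb, GRCh38), with the intervals of the PRMT1 library above and protein-coding genes below, the named gene in orange. Wide intervals lie over an end of CD163 (13484 bp) and over TYROBP, HCST and an end of NFKBID (12268 bp). None is listed in the stretches drawn around ELF5 and CGA.

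Markers of the other cell types that villous tissue can hold had intervals at or below the random ranges. Endothelial markers had them at 16 of 20 (80%, random 10 to 18), with the highest scores at ENG (1000), FLI1 (866), ESAM (487) and ERG (317), and none at VWF or ROBO4. Stromal fibroblast markers had them at 9 of 20 (45%, random 11 to 18), among them VIM (6885 bp), ACTA2 (5162 bp), TWIST1 (3194 bp) and PDGFRA (2838 bp), with none at COL3A1 or DCN. Nearest-gene credit gives the intervals at ENG, FLI1, VIM and ACTA2 to neighbouring genes. Erythroid markers had them at 4 of 20 (20%, random 8 to 16), namely ANK1, TAL1, KLF1 and HBZ, with none at HBA1 or HBA2. Lymphoid markers had them at 10 of 20 (50%, random 10 to 18), the highest score being 558 at CD8A, then CD2 (122), IL7R (113) and TBX21 (77), with none at CD3D or GNLY. Neuronal genes, from a tissue outside the placenta, had them at 9 of 25 (36%, random 14 to 22), with the highest scores at SLC17A7 (1000), SLC12A5 (852), GABRB2 (527) and TUBB3 (395), and none at SNAP25 or GRIN2A. In the 15251 intervals with the highest score, 5 endothelial, 4 stromal, 1 lymphoid and 4 neuronal genes had one, and at the score ceiling no erythroid gene did. With a window of 5 kb, 16 lymphoid genes had one, and with the centre rule 9 endothelial genes did, and FLI1, VIM, TAL1, SLC17A7 and GABRB2 had none. Counting any interval in the gene or its flanks gave 17 endothelial, 13 stromal, 4 erythroid, 14 lymphoid and 13 neuronal genes.

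PRMT1 intervals lay at nearly all genes of arginine methylation and at every gene of the substrate list, as they did for several lists described below. Of 21 arginine methyltransferases and cofactors, 20 (95.2%) had one (random 11 to 18). The widest were at the PRMT1 partners BTG1 (12413 bp) and BTG2 (6815 bp), followed by PRMT2 (5434 bp) and ERH (5249 bp), and the exception was PRMT8. With nearest-gene credit 15 of the 21 had one, and the intervals at BTG1, ERH, PRMT5, CHTOP and PRMT7 went to neighbouring genes. The PRMT1 gene itself (chromosome 19, 49676153 to 49688447) had an interval of 3355 bp from 49675572 to 49678926, at the score ceiling, which is lost when the interval's centre has to lie inside the window. All 25 genes of the list named for RNA-binding PRMT1 substrates had an interval (random 14 to 22), with a median width of 4435 bp. The list includes SERPINH1 (2252 bp), which encodes a collagen chaperone, so its name may not describe every member. With the interval's centre required inside the window, 12 of the 21 methyltransferases and cofactors had one. In the substrate list, without that requirement, the widest intervals were at HNRNPA2B1 (10170 bp), HNRNPA1 (7705 bp), HNRNPU (6374 bp) and SAFB (6106 bp). Under nearest-gene credit 21 of the 25 substrate genes had one, and HNRNPU, G3BP1, HNRNPK and RBM15 lost theirs.

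Genes of protein synthesis and RNA processing were almost completely covered. Large ribosomal subunit proteins had a boundary interval at 46 of 47 genes (random 22 to 35), the exception being UBA52, with RPL23A (5757 bp), RPL7 (5573 bp), RPL19 (4907 bp) and RPL41 (4901 bp) widest. Small ribosomal subunit proteins had one at all 32 (random 13 to 24), RPS9 (8840 bp), RPS12 (4655 bp), RPS19 (4371 bp) and RPS18 (4148 bp) leading. So did all 20 cytosolic aminoacyl-tRNA synthetases (random 12 to 19), with KARS1 (6221 bp), WARS1 (5479 bp), YARS1 (4540 bp) and GARS1 (3697 bp) widest. All 30 spliceosome components had one (random 17 to 26), the widest at SRSF3 (7470 bp), SRSF2 (6998 bp), SF3A2 (5687 bp) and SF3B1 (5380 bp). With any interval in the gene or its flanks counted, all 47 large subunit genes had one. Nearest-gene credit left one at 39 of 47 large and 27 of 32 small subunit genes. It left one at 17 of 20 synthetases and 26 of 30 spliceosome components, and KARS1 and SRSF2 lost theirs.

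Genes of the cell cycle and genome maintenance were covered to a similar degree. DNA replication and G1/S genes had an interval at 34 of 36 (random 22 to 32), among them SLBP (5556 bp), ORC6 (5376 bp), RRM2 (5128 bp) and RFC2 (4161 bp), with none at ORC1 or UHRF1. G2/M and mitosis genes had one at 31 of 32 (random 19 to 28), led by SMC4 (8593 bp), NCAPG (6688 bp), NCAPD2 (5298 bp) and KIF11 (4509 bp). SMC2 lacked one at its boundaries but had one of 5182 bp inside the gene. The NCAPD2 interval is the one listed at GAPDH, and with nearest-gene credit NCAPD2 kept one of 3269 bp. DNA damage repair genes had one at 29 of 30 (random 19 to 28), led by ATM (6897 bp), MDC1 (6777 bp), LIG4 (6726 bp) and MLH1 (5963 bp). RPA3 lacked one at its boundaries but had one of 3226 bp inside the gene. With any interval in the gene or its flanks counted, all 36 replication, 32 G2/M and 30 repair genes had one. All 40 replication-dependent histone genes had one (random 11 to 23), with a median width of 4496 bp. H3C4, H2AC7 and H2BC7 shared an interval of 7024 bp and H3C12 lay in one of 6625 bp. Neighbouring histone genes are near-identical in sequence and often share an interval, so their count is uncertain. With credit only to the nearest gene, DNA damage repair genes had an interval at 17 of 30 and histone genes at 23 of 40, and among intervals at the score ceiling replication genes had one at 29 of 36 and G2/M genes at 27 of 32 (17 and 19 among the 7625 widest of these). All 32 chromatin modifiers had one (random 20 to 29), and KDM6B (12286 bp), ARID1A (11538 bp), KMT2A (7248 bp) and TET2 (6822 bp) had the widest. Nearest-gene credit gives the intervals at ORC6, MDC1, MLH1 and KDM6B to neighbouring genes.

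Metabolic, growth and interferon genes also exceeded the random ranges. Oxidative phosphorylation genes had an interval at all 39 members (random 20 to 31), led by ATP5F1B (9227 bp), NDUFV2 (6637 bp), NDUFB3 (5301 bp) and NDUFS2 (5036 bp). Glycolysis and hypoxia genes had one at 28 of 30 (random 17 to 26), led by HIF1A (9214 bp), ADM (7038 bp), EGLN1 (6435 bp) and PKM (6170 bp). HK1 and CA9 had none at their boundaries but had intervals of 3597 and 1074 bp inside the gene. All 26 mTOR and growth signalling genes had one (random 15 to 24), led by PTEN (10434 bp), FOXO3 (9991 bp), MYC (6697 bp) and IGF1R (6547 bp). Interferon-stimulated genes had one at 26 of 28 (random 14 to 23), led by IFIT3 (7273 bp), IFIH1 (7210 bp), IFI44L (6586 bp) and IRF1 (5920 bp), with none at ISG20 or IFI27. ISG20 had an interval of 2490 bp inside the gene. Nearest-gene credit gives the intervals at HIF1A, ADM and PTEN to neighbouring genes. With the interval's centre required inside the window, the count was 15 for each of the glycolysis and hypoxia, mTOR and interferon lists.

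Wnt, Hippo and imprinted genes lay nearer to the random lists. Wnt pathway genes had an interval at 22 of 24, at percentile 97.8 of random lists (14 to 22), with the highest scores at GSK3B (7351 bp), CTNNB1 (6004 bp), FZD5 (5484 bp) and DVL3 (4701 bp) and none at TCF7 or TNFRSF19. TCF7 and TNFRSF19 had intervals of 1317 and 2126 bp inside the gene. Hippo pathway and YAP target genes had one at 21 of 24 (87.5%), at percentile 92.2, with STK3 (7548 bp), STK4 (6519 bp), AXL (5503 bp) and MAP4K4 (5307 bp) widest. The AXL interval is the one listed at HNRNPUL1, and with nearest-gene credit AXL kept one of 3571 bp and STK3 none. Neither AMOTL1 nor ANKRD1 had one at a boundary, although AMOTL1 had one of 2857 bp inside the gene. Imprinted genes had one at 19 of 26 measured (73.1%), at percentile 70.7. Among these SLC67A1 (5164 bp), ZFAT (4456 bp), KCNQ1 (3850 bp) and IGF2R (3832 bp) had the highest scores, and IGF2 and DLK1 had none. Among intervals at the score ceiling the counts were 12 for Wnt, 13 for Hippo and 8 for imprinted genes, and with the centre rule 13 for Hippo genes. In total 17 of the 27 lists lay in the highest 2.5% of random lists by percentile, with ties at the middle rank, and 4 in the lowest 2.5%. The Wnt list is among the 17 although its count equals the upper limit of its random range. With the interval's centre required inside the window, 9 lay in the highest 2.5%, and with the 15251 highest-scoring intervals, 7 lay in the lowest.

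**Figure D4:**
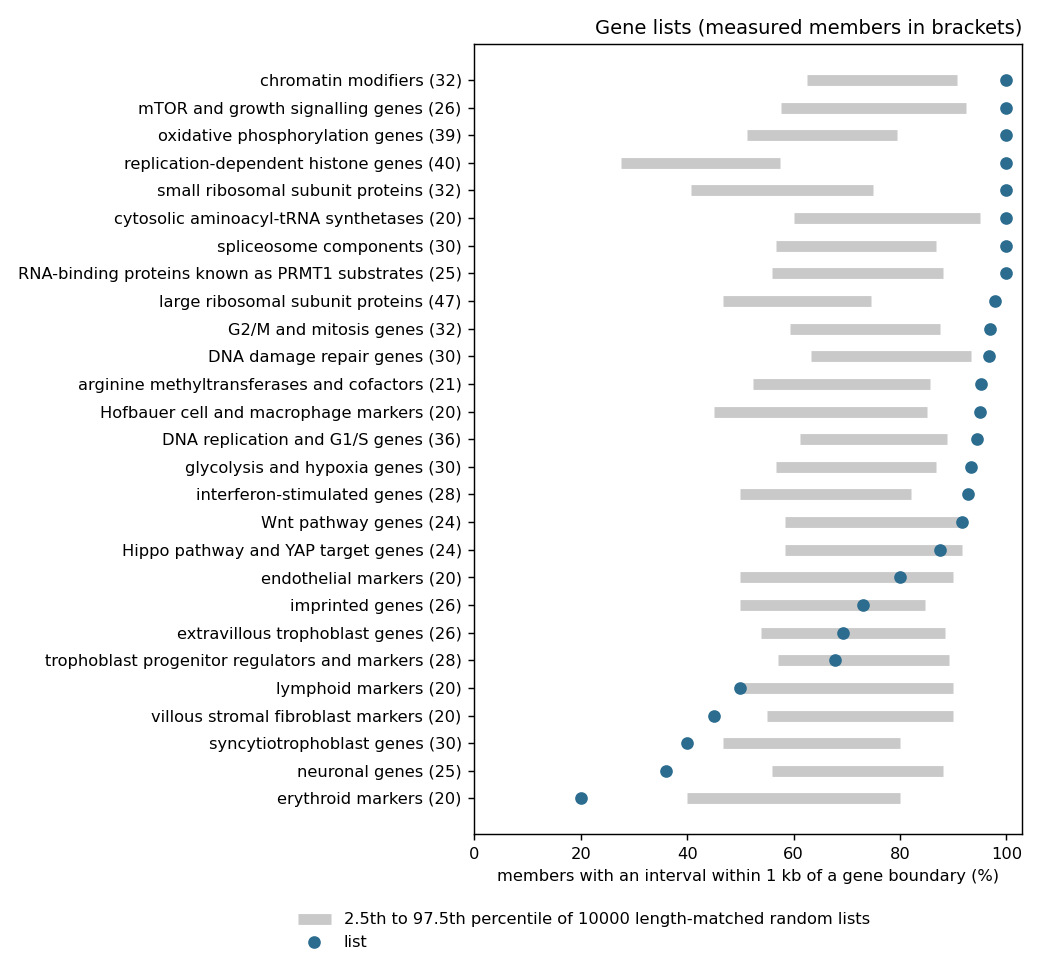
Share of the measured members of each of the 27 gene lists with an interval within 1 kb of a gene boundary (x axis, percent), as points, with the range of 10000 random lists matched on gene length, without their lowest and highest 2.5%, as grey bars. Points of 17 lists lie in the highest 2.5% of random lists by percentile, up to 100%, the Wnt list at the end of its bar, and those of the syncytiotrophoblast, stromal fibroblast, neuronal and erythroid lists lie in the lowest 2.5%.

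The 25 genes with the highest-scoring boundary intervals, ties at the ceiling of 1000 being ordered by width, had intervals of 12559 to 19654 bp. The widest lay in the HOXB cluster of developmental transcription factors (chromosome 17, 48575136 to 48594789), with its nearest protein-coding boundary at HOXB3, and touched windows of HOXB4, HOXB5 and HOXB6 too. It was followed by CFLAR (18923 bp), an inhibitor of caspase-8 (chromosome 2, 201114672 to 201133594), and by ZEB2 (18499 bp), a zinc-finger repressor (chromosome 2, 144507184 to 144525682). Other transcription and chromatin regulators were NR2F2 (16828 bp), JUNB (15706 bp), ZNF503 (14744 bp), KMT2E (14489 bp) and TNRC18 (12560 bp). Genes of growth control were SPRED1 (16509 bp), an inhibitor of Ras signalling, and CDKN1B (13520 bp), which encodes the cell cycle inhibitor p27. Receptors, transporters and membrane proteins were SLC40A1 (16172 bp), the iron exporter ferroportin, SLC39A1 (12681 bp), a zinc transporter, PTGER4 (13076 bp), a prostaglandin E2 receptor, NRP1 (12872 bp), PLXDC2 (13883 bp), TM9SF2 (13398 bp), the endocytic adaptor DAB2 (13630 bp) and EVI2B (14650 bp), which lies inside NF1. CD163 (13484 bp) and FCGR3A (12559 bp), an Fc receptor of macrophages and natural killer cells with a near-identical neighbour, were also among them. MGAT1 (18380 bp), an enzyme of N-glycan synthesis, and EIF4A1 (13569 bp), a translation helicase whose interval also covers CD68, completed the well-described genes. The interval credited to TSPOAP1 (12698 bp) extended over the microRNA gene MIR142. Those credited to the uncharacterised loci LOC124901234 (17200 bp) and LOC128966704 (12658 bp) lay over QKI and NR3C1. With credit to the nearest boundary of any protein-coding or lncRNA gene, the intervals at CFLAR, ZEB2, NR2F2, EIF4A1, CD163 and TSPOAP1 went to neighbouring genes and HOXB3 kept one of 2270 bp. With the interval's centre required inside the window, 19 of the 25 genes had no interval, LOC124901234 kept one of 382 bp, and only ZNF503, EVI2B, EIF4A1, TM9SF2 and TNRC18 kept theirs.

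Hofbauer markers were concentrated among the genes with the widest boundary intervals. Of all protein-coding genes, 1001 (5.01%) had an interval of at least 6062 bp. Of the 20 Hofbauer cell and macrophage markers, 12 (60%) did, 12 times the share of all genes. Nearest-gene credit gives the intervals at CD68, CD163 and TYROBP among these to neighbours, and VSIG4 then keeps one of 2882 bp. Trophoblast progenitor genes were represented by 1 of 28 (3.57%), GATA2, whose interval nearest-gene credit gives to a neighbour, and syncytiotrophoblast genes by none of 30. Shares were 23.1% for mTOR and growth signalling genes, 20% for histone genes and 18.8% for chromatin modifiers.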

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

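All intervals at the score ceiling, placement over whole chromosome spans, nearest-gene credit, counting any interval inside a gene, matching on neighbouring boundaries and the shortened syncytiotrophoblast list were tests chosen only after the results were seen. The excess at gene boundaries kept its direction in every setting run, and the Hofbauer list carried intervals more often than the trophoblast progenitor list in every setting except the one that requires the interval's centre inside the window. The upper set is the highest-scoring 50% (15251 intervals), the ceiling set all 10463 intervals tied at a score of 1000, and the widest set the 7625 widest of these, taken where the highest-scoring 25% had been intended. The widest set is chosen by width, so its widths and list values partly restate width. Median widths were 2696, 3132 and 3621 bp, with 46.6, 37.3 and 31.6 Mb covered. Joining intervals gave a median width of 1763 bp and 60.1 Mb. The boundary share was 62.8% (upper set), 69.5% (ceiling set), 66.4% (widest set), 28.1% (500 bp window), 65.7% (5 kb), 50.6% (any overlap) and 39.3% (at least 50% of the interval inside). The fold over random was 11.5, 12.7, 12.4, 10.004, 3.14 and 5.29 in the first 6 of these. The median score at boundaries exceeded that elsewhere by 0 in these 3 sets, where the ceiling fixes both medians, and by 888 (autosomes), 857 (500 bp), 748 (5 kb), 911 (any overlap) and 880 (at least 50% inside). Genes with a boundary interval numbered 10296 in the ceiling set, 8022 in the widest set and 11300 to 15176 elsewhere. Lists in the highest 2.5% of random lists numbered 9 with the centre rule, and lists in the lowest 2.5% numbered 7 in each of the 3 sets. The syncytiotrophoblast list without its near-identical families stood at percentile 10.9, which ends its place in the lowest 2.5%.

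The Hofbauer minus trophoblast progenitor share was 45.7 points (upper set), 65.7 (ceiling and widest sets), 21.7 (autosomes), 20 (5 kb), 26.4 (nearest gene) and 21.4 (any interval in the gene), and reversed to -21.4 with the centre rule, which by construction leaves out wide intervals whose centre lies over 1 kb from a boundary. The ratio of widths was 1.96 (upper), 1.51 (ceiling and widest), which selection of wide intervals compresses, and 2.92 (autosomes), 2.87 (500 bp), 2.56 (centre), 2.65 (nearest gene) and 2.21 (any interval in the gene). The cause of the other shifts was not tested. Of 298 counts of single lists under alternatives, 240 stayed within the range set for a count and 58 moved, 18 of them in the widest set, 16 in the ceiling set and 10 under the centre rule. Of 468 widths at named genes, 378 stayed and 90 moved, 40 of them under the centre rule. Alternatives that need sequence, strand or transcripts (CpG matching, GC-matched placement, the 5′ end alone, all motif settings) were not run, nor were autosome-only totals of intervals and genes. No paired analysis was possible because each antibody has 1 library and the result comes from no test. Without read counts, weak intervals cannot be weighed by depth, and a gene without an interval was not detected at the authors' threshold.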

Other observations

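The 6 added lists, the gene families and the tests against neuronal and hepatocyte genes and on neighbouring boundaries were chosen only after the results were seen. The 6 lists were written without looking up their members, and genes already seen among the widest intervals were kept out of the myeloid list. Genes named below were picked after their values were seen.

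Gene families differed sharply in how often they had an interval of the PRMT1 library, with no IgG background set against it. All 33 RNA polymerase subunits, 75 of 77 mitochondrial ribosomal proteins and 37 of 40 proteasome subunits had a boundary interval, and so did 462 of 517 ZNF genes (89.4%). Families silent in most tissues had few, with 7 of 392 olfactory receptors (1.79%, Wilson 95% interval 0.868 to 3.64), none of 94 keratin-associated proteins and none of 25 type 2 taste receptors. Keratins, several of which epithelia including trophoblasts express, had one at 5 of 55 (9.09%, 3.95 to 19.6), KRT8 and KRT18 among them through a shared interval. None of the 10 pregnancy-specific glycoproteins, made in quantity by the syncytiotrophoblast, had one, although their near-identical copies make reads hard to place. All 12 HOXA entries, among them the readthrough locus HOXA10-HOXA9, and 8 of 10 HOXB genes had an interval. The median width was 13485 bp at the HOXB genes with an interval, but 4 of them (HOXB3, HOXB4, HOXB5 and HOXB6) shared the same interval of 19654 bp. For both HOXC and HOXD, 6 of 9 had one. Of 10 toll-like receptors 9 had one, with a median width of 4368 bp. The widest intervals outside protein-coding genes lay over the nuclear lncRNA genes NEAT1 (18714 bp) and MALAT1 (12698 bp), and wide intervals also lay inside the transcription factor genes MEF2C (16147 bp) and RUNX1 (13310 bp).

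The added epithelial and myeloid lists differed in width and score more than in count. Epithelial genes had an interval at 28 of 32 (87.5%) with a median width of 2003.5 bp, and myeloid genes at 30 of 32 (93.8%) with 5034 bp, a median width above all 10000 length-matched lists. In the 15251 intervals with the highest score, epithelial genes had one at 12 and myeloid genes at 29, and among intervals at the score ceiling 6 and 27, where score and width rise together. Members of the myeloid list with broad intervals included CD53 (8944 bp), TLR4 (8059 bp), IKZF1 (7444 bp), IRF8 (6805 bp), CEBPA (6574 bp) and SPI1 (5940 bp). With nearest-gene credit the interval at CD53 went to a neighbouring gene. Endothelial genes had one at 17 of 25 (68%), granulocyte genes at 9 of 20 (45%), T, B and NK cell genes at 10 of 24 (41.7%) and hepatocyte genes at 4 of 20 (20%). Among intervals at the score ceiling the counts were 6 for endothelial, 2 for granulocyte, 2 for T, B and NK cell and 1 for hepatocyte genes.

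In the library labelled as cytotrophoblasts, Hofbauer markers carried boundary intervals more often than trophoblast progenitor genes, except with the interval's centre required inside the window. That requirement turned the difference to -21.4 points and gave 11 of 32 myeloid against 20 of 32 epithelial genes. By construction it leaves out wide intervals whose centre lies over 1 kb from a boundary, so it cannot separate a lower count from greater width. Credit through a neighbouring gene is argued against for the Hofbauer list by a difference of 26.4 points with credit to the nearest gene only. However, CD68, CD163 and TYROBP lose their interval under that rule, in which lncRNA genes also compete. The CD163 interval touched the window of no other protein-coding gene. The added lists then had 26 of 32 myeloid against 27 of 32 epithelial genes. A signal at every start site, whatever the cell type, is also argued against. Hofbauer and myeloid genes exceeded neuronal and hepatocyte genes by 65.3 points (94.2% of 52 against 28.9% of 45). This gap does not address background signal at open start sites, against which the IgG library, not analysed here, would have to be set. Start sites inside trophoblast genes cannot be told apart as a partial cause, because the pooled Hofbauer and myeloid genes exceeded trophoblast progenitor and epithelial genes by 15.9 points at boundaries and by 11.7 with any interval in the gene (100% of 52 against 88.3% of 60), a gap too small from the start to decide, and Hofbauer markers alone exceeded progenitor genes by 21.4 under that rule. A candidate explanation is chromatin of Hofbauer cells or other macrophages beside that of trophoblasts, which percentile 99.945 of the added myeloid list's count among length-matched lists is consistent with, as are the broad intervals at PTPRC (9032 bp), AIF1 (8770 bp) and F13A1 (8409 bp), which nearest-gene credit leaves in place, although selection for ITGA6 would be expected to remove such cells. PRMT1 may instead occupy these genes inside cytotrophoblasts, which percentile 98.3 of the epithelial list's count leaves open without separating it from a mixture, and neither expression nor the IgG library was analysed here.

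Macrophage genes were also over-represented among the genes with the widest boundary intervals, although the very widest lay at other genes. Gene length is argued against, since the median width at the 52 Hofbauer and myeloid genes, 5624.5 bp, stood at the 100th percentile of length-matched lists, whose highest 2.5% began at 2774.5 bp, while trophoblast progenitor and epithelial genes had 1964.5 bp. Joining of crowded start sites is argued against by the 100th percentile among lists matched on neighbouring boundaries, and the ratio of 1.63 among genes with no other boundary nearby (4443.5 bp against 2731 bp) points the same way, but rests on 4 macrophage genes and decides nothing alone. Myeloid genes were 5.61 times as frequent among the widest as all genes, which is consistent with macrophage chromatin in the library and could also reflect PRMT1 spread over these genes in trophoblasts. None of the 20 Hofbauer and 32 myeloid genes was in another list, and how many of them trophoblasts express was not analysed here.

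The third pattern is the signal at tRNA genes, at 54.2% of which an interval lay. Intervals of nearby protein-coding genes are argued against as the whole source, since 109 of 277 tRNA genes lying over 10 kb from any protein-coding gene, 39.4% (33.8 to 45.2), had one. No biological explanation was tested, and the IgG library, which would show background at these repeated and open sites, was not analysed here.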
